A study of Homo sapiens with 24 samples.

How the data were processed

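Cytosolic RNA and polysome-associated RNA of MCF7 cells were sequenced for 3 treatments with 4 replicates each, 24 libraries in 6 groups, and group and replicate number were taken from the sample titles. The labels hold 3 conflicts that were read as slips: the protocol gives DMSO a dose of 4.2 nM, the characteristics of insulin and torin1 cytosolic replicate 4 name torin4, and the title of DMSO polysome replicate 3 is spelled unlike the others. The counts were made by the authors with rpkmforgenes on HISAT alignments against the refGene annotation of hg19, and are deposited unscaled, per gene row, per the file headers. The RPKM values in the same table were scaled by the authors to reads that match mRNA and to transcript length, per the file headers. Versions of HISAT and rpkmforgenes were not given. The recorded arguments name 40 alignment files, of which the table holds 24, and 0 columns of the table were left unused. No strand option is among the arguments, so antisense transcription could not be told apart, and no genome was at hand, so no coordinates were used. Of 23600 rows, 2366 carry several gene names, which can be overlapping genes or copies that share their sequence. Of the tested rows, 1130 carry several names after those of small RNAs, antisense transcripts and readthrough transcripts were dropped.

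The plan made before the data were examined assumed RPKM values and limma. The table also holds counts, so the main test became the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling factors (0.95 to 1.04), and limma 3.58.1 on log2(RPKM + 0.5) became an alternative. Rows with a mean RPKM of at least 1 were tested (11553). All 24 libraries were fitted with 6 group means and no replicate term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Insulin was compared with DMSO, insulin and torin1 with insulin, and insulin and torin1 with DMSO, in each fraction and for translational efficiency, which is the interaction of treatment and fraction. Genes were put in classes built from these calls, not from the tool named in the series title, analysis of partial variance, which was run as an alternative. A translation class gene passed in efficiency and in polysome-associated RNA in the same direction, a buffering class gene passed in efficiency and in the opposite direction in cytosolic RNA but not on polysomes, and an abundance class gene passed in both fractions but not in efficiency.

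The 26 gene lists were written from general knowledge, and 23 with at least 5 measured members were tested with camera of limma at a preset correlation between genes of 0.01. The tests were adjusted together within each comparison and readout, and repeated with an estimated correlation. Of 847 symbols on the lists, 809 matched a row. The lists not tested or not described in the report gave these results: 4 of 12 fibroblast genes were measured (highest COL5A1, 2.35 RPKM), 1 of 10 blood cell genes (CD68, 1.16 RPKM) and 0 of 26 symbols for mitochondrially encoded mRNAs (2 names for each gene). Among basal epithelial genes 5 were measured with a median of 2.68 RPKM (adjusted p = 0.93 for insulin on polysomes; with torin1 against DMSO in cytosolic RNA a median change of 0.56, adjusted p = 0.031, or adjusted p = 0.25 with an estimated correlation), and among luminal ones 10 with a median of 139 RPKM (KRT18/KRT8 highest at 3770, adjusted p = 0.8). FBN1 of the fibroblast list rose by 0.84 with torin1 against insulin in polysome-associated RNA.

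Named genes followed a rule: the 6 largest rises and 6 largest falls of each comparison and readout with a mean RPKM of at least 10 and groups that do not overlap, the 4 members with the smallest p of each list that passed or had 20% of members passing, and 20 genes set beforehand. Small RNAs were left out, as were unnamed loci where more than 6 others qualified.

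Replicate numbers come from the titles. Same-numbered libraries of compared groups were taken as pairs where every correlation of their deviations from the group mean was over 0.1. This held for insulin against DMSO on polysomes (r 0.329 to 0.792), for torin1 against insulin on polysomes (0.193 to 0.841), in cytosolic RNA (0.481 to 0.912) and in efficiency (0.193 to 0.912), and for torin1 against DMSO on polysomes (0.215 to 0.856). It did not hold for comparisons with DMSO cytosolic RNA (lowest r -0.287 to -0.29). Counts or calls with a replicate block are given beside the former where the block changed a call or moved a count of calls by more than 1.5 times.

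The pipeline was tested on simulated data of 11553 genes with the dispersion of these libraries. In polysome-associated RNA, changes of log2 1 were recovered in 83.5% of 91 genes and changes of 0.58 in 48.6%, with 5 false calls among 11353 unchanged genes. For efficiency these were 64.8%, 21.1% and 2 false calls, and in cytosolic RNA, where no change was simulated, edgeR called 0 of 11553 genes. Each gene was drawn independently. The simulation thus left out the component, shared by same-numbered libraries, that held 75.7% of the within-group variance. Its false calls do not give the error rate in the real libraries. Depth was 18.5 to 74.5 M gene counts per library, so the precision of most tested genes was set by replicate spread.

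Alternatives were other pseudocounts, filters, scalings and variance priors, a replicate block, fits of the 8 compared libraries, paired lysates, analysis of partial variance, DESeq2 1.42.0, median-ratio factors, a correction for GC content and transcript length (GENCODE 29 transcripts matched by RefSeq accession), and leaving out single libraries. A lysate here means the cytosolic and the polysome library of the same treatment and number, though the labels do not say that these came from 1 lysate. The 35 splits of 8 lysates into groups of 4 gave the counts chance can reach. Figures were drawn with matplotlib 3.10.9. No library was left out of the main test.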

Results

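RNA was sequenced from MCF7, an established human breast adenocarcinoma line that expresses the oestrogen receptor. The cells were starved of serum for 12 h and then kept for 4 h with the solvent DMSO, with insulin at 4.2 nM, or with insulin and torin1 at 250 nM. Torin1 binds the active site of the kinase mTOR, which insulin signalling activates. Libraries came from cytosolic RNA and from polysome-associated RNA, the mRNA that sediments with several ribosomes, so that 6 groups of 4 libraries (24 in all) were available. Gene counts per library were 25.7 to 62.5 M (megacounts) in DMSO cytosolic RNA, 30.3 to 47 M with insulin and 18.5 to 42.1 M with insulin and torin1. In polysome-associated RNA they were 52.7 to 67.2 M, 54.8 to 74.2 M and 50.5 to 74.5 M. Replicates varied more than counting error gives, with a chi-square per degree of freedom of 4.797 to 430. The lowest value was between DMSO cytosolic replicates 2 and 3, and the next, 15.34, between insulin cytosolic replicates 3 and 4. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these libraries. Changes are log2 fold changes ± SE with n = 4 libraries in each group, and translational efficiency is the polysome change minus the cytosolic change. A member named because a count was 5 or fewer was chosen after its values were seen.

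The comparison of insulin with DMSO asked which mRNAs changed in amount, and which in polysome association, when starved cells received insulin. Genes of the FOXO and insulin feedback list fell in both fractions, genes of ribosome biogenesis rose in both, and ribosomal protein mRNAs rose in polysome-associated RNA. KLHL24, a substrate receptor of a ubiquitin ligase, had the largest fall among the named genes, -2.15 ± 0.10 in polysome-associated RNA (0.226-fold, adjusted p = 7.1e-12) and -1.89 ± 0.10 in cytosolic RNA (0.269-fold). IRS2, an adaptor of the insulin receptor, fell to 0.351-fold (-1.51 ± 0.10) in polysome-associated RNA, and its cytosolic RPKM went from 2.33 ± 0.119 (SD) to a level 0.359-fold as high. NOP56, a core protein of box C/D small nucleolar ribonucleoproteins, rose by 0.87 ± 0.04 (1.83-fold, adjusted p = 1.2e-11) in polysome-associated RNA and by 0.65 ± 0.04 in cytosolic RNA.

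Of 28 measured members of the FOXO and insulin feedback list, 19 fell, 1 rose and 8 did not pass in polysome-associated RNA (20 fell and 1 rose adjusted over the list alone). In cytosolic RNA 18 fell and 0 rose (21 and 1 adjusted over the list alone), and the list tests gave adjusted p = 1.3e-21 and 2.8e-24. FOXO3, a transcription factor of this programme, fell by 0.63 ± 0.04 in polysome-associated RNA, TXNIP, an inhibitor of thioredoxin and glucose uptake, by 1.16 ± 0.09, and the member that rose was BNIP3 (0.19 ± 0.07). Of 57 ribosome biogenesis genes, 42 rose and 0 fell in polysome-associated RNA (48 rose adjusted over the list alone), and 40 rose and 0 fell in cytosolic RNA (47 rose and 1 fell adjusted over the list alone). NOP2, an rRNA methyltransferase, rose by 0.95 ± 0.06, RRP1B, a nucleolar protein, by 0.69 ± 0.04 and NOP14 by 0.56 ± 0.05 (list adjusted p = 6e-22 in polysome-associated and 2.3e-23 in cytosolic RNA). Of 79 ribosomal protein genes, 60 rose and 0 fell in polysome-associated RNA (70 rose adjusted over the list alone, adjusted p = 1.3e-21), and 15 of 30 other TOP mRNAs rose and 0 fell (16 adjusted over the list alone, or 25 rises and 1 fall with a replicate block). TOP mRNAs start with a C followed by pyrimidines and encode ribosomal proteins and other parts of the translation apparatus. The call of the other TOP mRNAs was lost with another correlation, at adjusted p = 0.053 with an estimated correlation. RPL7A rose by 0.73 ± 0.08, RPS3 by 0.86 ± 0.10, SLC25A5, the ADP/ATP carrier of mitochondria, by 0.63 ± 0.04, and the elongation factor EEF1A1 by 0.51 ± 0.06, a call that did not pass with quantile normalisation in limma. In cytosolic RNA 10 ribosomal protein genes fell and 0 rose, but adjusted over the list alone 0 fell. The median there was -0.12 and the mean 0, and the test gave adjusted p = 0.031, or adjusted p = 0.57 with an estimated correlation.

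Insulin also moved metabolic and cell cycle genes. Of 36 members of the ATF4 and amino acid supply list, 15 rose in polysome-associated RNA and the transporter gene SLC38A2 fell (-0.85 ± 0.09), 15 and 2 adjusted over the list alone or 27 and 5 with a replicate block, with adjusted p = 0.00052, or adjusted p = 0.053 with an estimated correlation. In cytosolic RNA 11 rose and SLC38A2 fell (14 and 1 adjusted over the list alone, adjusted p = 0.00026), among them MTHFD1L, of mitochondrial folate metabolism, at 0.80 ± 0.10. Of 30 measured SREBP targets, which make cholesterol and fatty acids, 9 rose and 0 fell in cytosolic RNA (13 adjusted over the list alone, adjusted p = 3.5e-05), including NSDHL (0.49 ± 0.06) and ACLY (0.56 ± 0.09). Of 19 glycolysis genes, 9 rose and 0 fell in cytosolic RNA (14 adjusted over the list alone), with HK2 at 0.59 ± 0.08 and PFKFB3 at 1.06 ± 0.17 (adjusted p = 8.5e-06, or adjusted p = 0.25 with an estimated correlation). Of 41 genes of G1/S and DNA replication, 16 rose and 1 fell (EIF4A2/RFC4, a row with several gene names) in cytosolic RNA (20 and 2 adjusted over the list alone), with adjusted p = 0.00031, or adjusted p = 0.22 with an estimated correlation. CDC25A, a phosphatase that activates cyclin-dependent kinases, rose by 0.69 ± 0.09 and cyclin E1, CCNE1, by 0.87 ± 0.12. Of 26 mitosis genes, 14 fell and UBE2C rose (0.29 ± 0.08) in polysome-associated RNA (16 and 1 adjusted over the list alone), with adjusted p = 0.00097, or adjusted p = 0.41 with an estimated correlation. ASPM, a spindle pole protein, fell by 0.68 ± 0.14 there.

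Among single genes outside these groups, TNFRSF12A, a receptor of the TNF family, rose by 1.42 ± 0.30 (2.68-fold, adjusted p = 0.0012) in polysome-associated RNA, followed by SRM, which makes spermidine (1.30 ± 0.32), and HMGA1, a chromatin protein (1.29 ± 0.32). CREBRF fell by 1.85 ± 0.14 and BMF, a promoter of apoptosis, by 1.52 ± 0.12. SLC7A5, a transporter of large neutral amino acids, rose by 1.58 ± 0.38 in cytosolic RNA, and this call did not pass without DMSO cytosolic replicates 2 and 3. Of the mRNAs often listed as sensitive to eIF4E, CCND1 (cyclin D1, 0.79 ± 0.13), ODC1 (ornithine decarboxylase, 0.53 ± 0.07) and VEGFA (0.73 ± 0.12) rose in polysome-associated RNA, BCL2 fell (-0.53 ± 0.09), and MYC was at -0.08 ± 0.15. The list of 17 as a whole had 5 rises and 3 falls (5 and 4 adjusted over the list alone, 7 and 6 with a replicate block, adjusted p = 0.6). The insulin receptor gene INSR fell by 0.77 ± 0.08.

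In all, 3808 of 11553 genes changed in polysome-associated RNA (1534 up, 2274 down). A replicate block gave 7739 and turned the balance, with 4118 up and 3621 down. In cytosolic RNA 2456 changed (1168 up, 1288 down), but 806 rose and 1361 fell with median scaling in limma, and 748 rose and 1456 fell with quantile normalisation. That count was 989 without DMSO cytosolic replicates 2 and 3, which stood apart from the other libraries of their numbers, 3699 without insulin cytosolic replicate 1, 1473 without replicate 3 and 1457 without replicate 4 of that group.

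**Figure D1:**
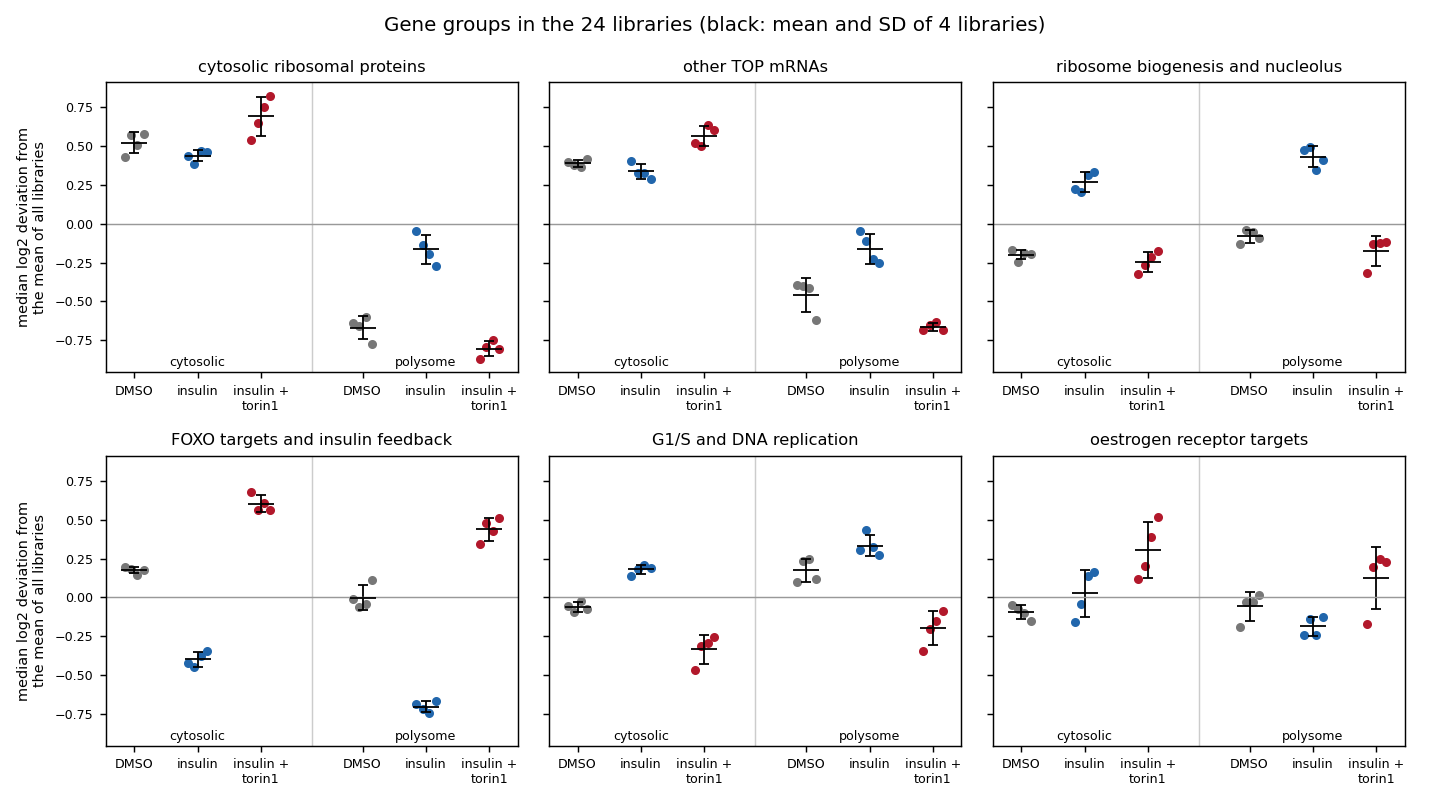
Median log2 deviation of 6 gene lists from their mean over the 24 libraries, for DMSO, insulin, and insulin with torin1 in each fraction; points are the 4 libraries of a group and black marks the mean and SD. FOXO and insulin feedback genes are lowest and ribosome biogenesis genes highest with insulin in both fractions, with 19 and 42 members passing in those directions in polysome-associated RNA.

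Translational efficiency under insulin rose for many mRNAs of the translation apparatus. RPL7A gained 0.86 ± 0.11 (1.82-fold, adjusted p = 0.00022), RPS3 0.93 ± 0.14, SLC25A5 0.53 ± 0.06, EEF1A1 0.66 ± 0.09, and EIF3F, a subunit of the initiation factor eIF3, 0.64 ± 0.09. Of 79 ribosomal protein genes, 32 rose and 0 fell in efficiency (51 rose adjusted over the list alone, adjusted p = 2.9e-110), and 8 of 30 other TOP mRNAs rose and 0 fell (16 adjusted over the list alone, adjusted p = 2.3e-39). Of the 85 genes whose efficiency changed (82 up, 3 down), 40 were in these 2 lists. With quantile normalisation in limma, 15 genes passed, and RPS3 and EIF3F were the named genes of this paragraph that kept their calls. Of 17 eIF4E-sensitive mRNAs 0 passed in efficiency, with CCND1 at 0.09 ± 0.19 and ODC1 at 0.03 ± 0.09. IRS2, with a large change in amount, was at -0.03 ± 0.14 in efficiency. The TOP snoRNA host genes, non-coding transcripts with the same kind of start, had 0 of 13 members passing and adjusted p = 0.00042, or adjusted p = 0.063 with an estimated correlation. The count of 85 was 30 without DMSO cytosolic replicates 2 and 3 and between 53 (without insulin cytosolic replicate 4) and 155 (without DMSO polysome replicate 2) when 1 library was left out, with 8 of 16 libraries moving it by more than 1.5 times. Unadjusted, 790 genes had p under 0.05.

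Across genes, which are not independent replicates, the polysome and cytosolic changes under insulin had r = 0.786. Of the changed genes, 1839 moved in the same direction in both fractions and did not pass in efficiency. Not passing does not show that efficiency was unchanged, as 21.1% of simulated efficiency changes of log2 0.58 were recovered. Another 78 changed in efficiency together with polysome-associated RNA (75 up, 3 down). A further 5 (IGBP1, HAUS4, THG1L, LOC100996634 and SCARNA7) fell in cytosolic RNA with higher efficiency and did not pass on polysomes. SCARNA7 is a small RNA, for which this value does not measure translation. Leaving out 1 library moved the 78 to between 52 (without insulin cytosolic replicate 4) and 139 (without DMSO polysome replicate 2), and 5 of 16 libraries moved it by more than 1.5 times. The 5 became 1 without insulin cytosolic replicate 3 and 15 without DMSO polysome replicate 1, and 15 of 16 libraries moved it by that much.

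**Figure D2:**
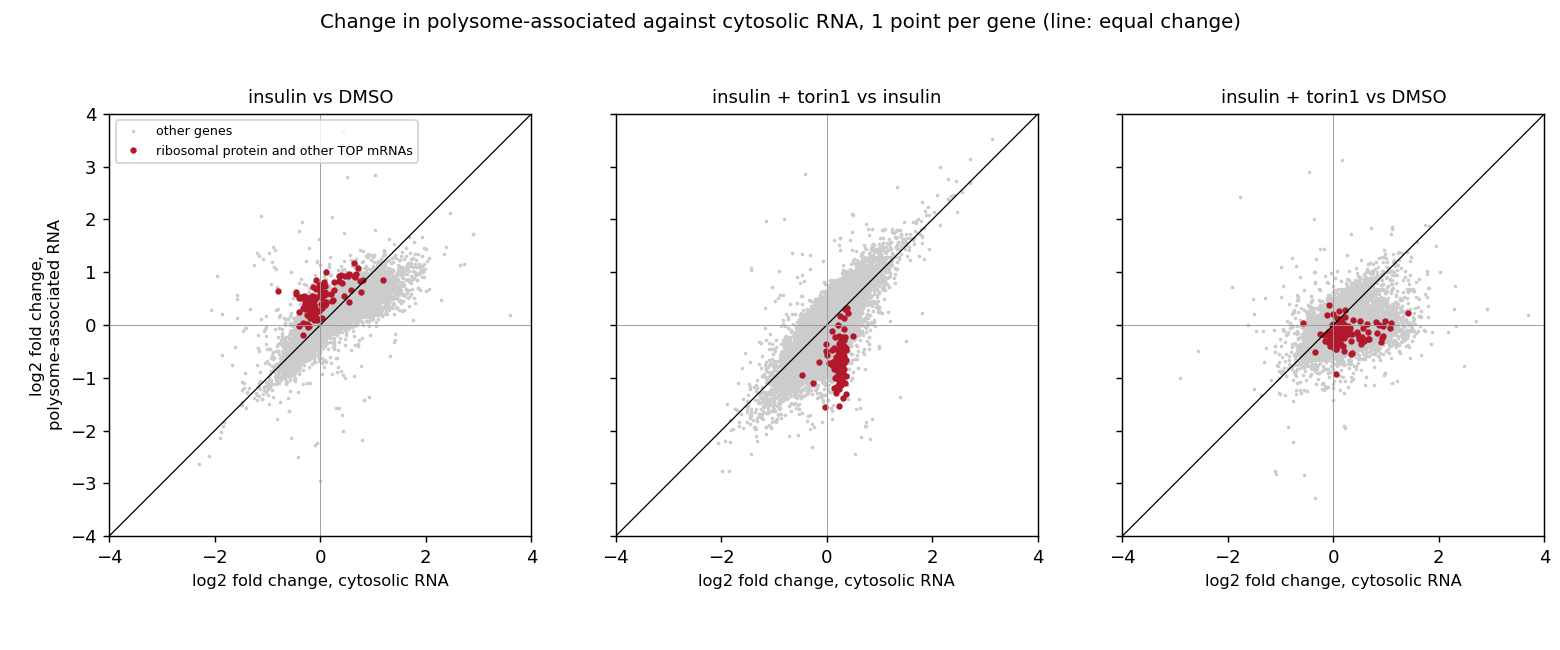
Log2 fold change in polysome-associated RNA (vertical) against cytosolic RNA (horizontal) for each tested gene in the 3 comparisons; the ribosomal protein and other TOP genes are red and the line marks equal change. The red points lie above the line for insulin against DMSO (median efficiency change 0.50) and below it for insulin with torin1 against insulin (-0.91); 1, 3 and 0 points lie outside the ±4 axes.

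The comparison of insulin and torin1 with insulin asked what changed when mTOR was inhibited during the insulin treatment. FOXO and insulin feedback genes rose, genes of ribosome biogenesis and G1/S fell, and TOP mRNAs fell on polysomes while most did not fall in cytosolic RNA. KLHL24 rose by 3.14 ± 0.10 in polysome-associated RNA (8.84-fold, adjusted p = 6.1e-15), from an RPKM of 6.13 ± 0.989 to 57 ± 5.15 (SD). IRS2 rose 5.5-fold (2.46 ± 0.11) there and 5.35-fold in cytosolic RNA. CDC25A fell to 0.212-fold (-2.24 ± 0.10) and CCNE1 to 0.254-fold (-1.98 ± 0.13) in polysome-associated RNA. MYC rose 3.15-fold (1.66 ± 0.16, adjusted p = 2.5e-08), from an RPKM of 11 ± 1.97 to 36.2 ± 5.61, and 3.16-fold in cytosolic RNA.

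In the FOXO and insulin feedback list 22 of 28 genes rose and 2 fell (BNIP3 at -0.29 ± 0.07 and PIK3R3 at -0.37 ± 0.07) in polysome-associated RNA, and 21 rose and 2 fell in cytosolic RNA. Adjusted over the list alone, 22 rose and 2 fell in each fraction (adjusted p = 5.3e-24 and 4e-32). FOXO3 rose by 1.30 ± 0.04 in polysome-associated RNA, and BCL6, a transcriptional repressor, by 1.51 ± 0.10 in cytosolic RNA. Ribosome biogenesis genes had 46 falls and 0 rises in polysome-associated RNA (48 and 1 adjusted over the list alone, adjusted p = 4.8e-14). They had 36 falls and 1 rise, POLR1D at 0.43 ± 0.09, in cytosolic RNA (39 and 1 adjusted over the list alone, adjusted p = 1.1e-14). NOP56 fell by 1.11 ± 0.04, NOP2 by 1.41 ± 0.06 and RRP1B by 0.90 ± 0.04 in polysome-associated RNA. In the G1/S and DNA replication list 27 of 41 genes fell and 2 rose (POLA1 at 0.48 ± 0.12 and RFC3 at 0.35 ± 0.09) in polysome-associated RNA, 27 and 3 adjusted over the list alone (adjusted p = 6.4e-09). In cytosolic RNA 26 fell and 1 rose (27 and 1 adjusted over the list alone, adjusted p = 6e-13). CDC6, which loads the replicative helicase, fell by 1.28 ± 0.08 in polysome-associated RNA and PCNA, the sliding clamp of DNA polymerases, by 0.76 ± 0.05 in cytosolic RNA.

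Glycolysis genes fell, 16 of 19 in polysome-associated RNA with 0 rises (17 adjusted over the list alone, adjusted p = 3.3e-05, or adjusted p = 0.24 with an estimated correlation). LDHA, lactate dehydrogenase, was at -0.77 ± 0.09 and GAPDH at -1.46 ± 0.19. Of 26 chaperone genes, 20 fell and 2 rose (HERPUD1 at 0.51 ± 0.08 and DNAJC3 at 0.25 ± 0.09), 21 and 2 adjusted over the list alone (adjusted p = 2.1e-08, or adjusted p = 0.062 with an estimated correlation). HSPA8, the constitutive Hsp70, fell by 1.88 ± 0.10 and its cofactor DNAJA1 by 1.32 ± 0.10. Of 32 proteasome subunit genes, 18 fell and 0 rose in cytosolic RNA (20 adjusted over the list alone, or 27 falls and 1 rise with a replicate block, adjusted p = 3.4e-05, or adjusted p = 0.12 with an estimated correlation), including PSMD11 at -0.58 ± 0.08. Of the ATF4 and amino acid supply list, 22 of 36 fell and 3 rose (SLC38A2, EPRS and NUPR1) in polysome-associated RNA, 23 and 3 adjusted over the list alone (adjusted p = 0.0019, or adjusted p = 0.062 with an estimated correlation). MTHFD1L fell by 1.42 ± 0.10 and SLC38A2 rose by 1.23 ± 0.09. Oestrogen receptor targets had 10 rises and 3 falls, FKBP4, RET and ADCY9, among 25 genes in cytosolic RNA (11 and 3 adjusted over the list alone, adjusted p = 0.0024, or adjusted p = 0.12 with an estimated correlation). PGR, the progesterone receptor, rose by 0.95 ± 0.08 there. Lysosome and autophagy genes had 12 rises and 2 falls (GLA and ATP6V0E1) among 37 in cytosolic RNA (13 and 2 adjusted over the list alone, 19 and 5 with a replicate block), with adjusted p = 0.01, or adjusted p = 0.12 with an estimated correlation. GABARAPL1, an autophagy protein, rose by 1.80 ± 0.15 there. Of 11 nuclear non-coding RNAs, 5 rose and 0 fell in polysome-associated RNA, led by NEAT1 at 1.56 ± 0.11 (5 and 0 adjusted over the list alone, adjusted p = 0.046, or adjusted p = 0.086 with a replicate block and adjusted p = 0.095 with an estimated correlation).

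Translational efficiency fell for TOP mRNAs when torin1 was added. SLC25A5 lost 1.51 ± 0.06 (0.351-fold, adjusted p = 9.5e-13), and its polysome-associated RPKM went from 487 ± 4.05 to 174 ± 8.16 (SD). YBX1, an RNA-binding protein, lost 1.63 ± 0.08 (adjusted p = 3.7e-11), GNB2L1, the ribosomal scaffold RACK1, 1.76 ± 0.19, and HSPA8 1.60 ± 0.13. Of 79 ribosomal protein genes, 54 fell and 0 rose (67 adjusted over the list alone, adjusted p = 1.2e-85), and 20 of 30 other TOP mRNAs fell and 0 rose (25 adjusted over the list alone, adjusted p = 1.5e-53). RPL7A fell by 1.36 ± 0.11, PABPC4, a poly(A)-binding protein, by 1.35 ± 0.09 and EIF3F by 1.35 ± 0.09. EEF1A1 fell by 0.96 ± 0.09, and this call did not pass with quantile normalisation.

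In polysome-associated RNA 64 ribosomal protein genes fell and RPL41 rose (68 and 1 adjusted over the list alone, adjusted p = 4.8e-15, or adjusted p = 0.051 with an estimated correlation). Of the other TOP mRNAs 24 fell and 2 rose (24 and 2 adjusted over the list alone, adjusted p = 1e-09), and the 2 were EIF4B at 0.32 ± 0.08 and TPT1 at 0.23 ± 0.08, of which TPT1 did not pass with median scaling in limma. In cytosolic RNA 22 ribosomal protein genes rose and RPS26 fell (21 and 1 adjusted over the list alone, 56 and 1 with a replicate block, adjusted p = 0.00036, or adjusted p = 0.3 with an estimated correlation). Of the other TOP mRNAs 13 rose and 0 fell there (14 adjusted over the list alone, 21 and 1 with a replicate block, adjusted p = 0.0035, or adjusted p = 0.23 with an estimated correlation). EIF3F rose by 0.37 ± 0.07, EIF3H by 0.32 ± 0.06 and PABPC1 by 0.50 ± 0.14 in cytosolic RNA. EEF1A1 was at 0.26 ± 0.06 in cytosolic RNA and at -0.03 with quantile normalisation, with which RPL12 (0.34 ± 0.06), PABPC1 and TPT1 (0.40 ± 0.08) did not pass. The TOP snoRNA host genes rose in cytosolic RNA, 8 of 13 against 2 falls, SNHG15 and RCC1/SNHG3 (9 and 2 adjusted over the list alone, adjusted p = 0.011, or adjusted p = 0.13 with an estimated correlation). GAS5 was at 0.62 ± 0.12.

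Efficiency of the eIF4E-sensitive mRNAs was again without a passing member in edgeR without a block, 0 of 17, but with a replicate block 4 rose and 3 fell. In the fit without it MYC was at 0 ± 0.21, CCND1 at -0.43 ± 0.19 (adjusted p = 0.00117 with the block) and ODC1 at -0.08 ± 0.09. In amount, CCND1 fell by 1.07 ± 0.13, CCND3 by 1.54 ± 0.29 and ODC1 by 0.84 ± 0.07 in polysome-associated RNA. Genes whose efficiency rose included the zinc finger gene ZNF799 (0.81 ± 0.17) and PLEKHF2, an endosomal protein (0.75 ± 0.14).

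**Figure D3:**
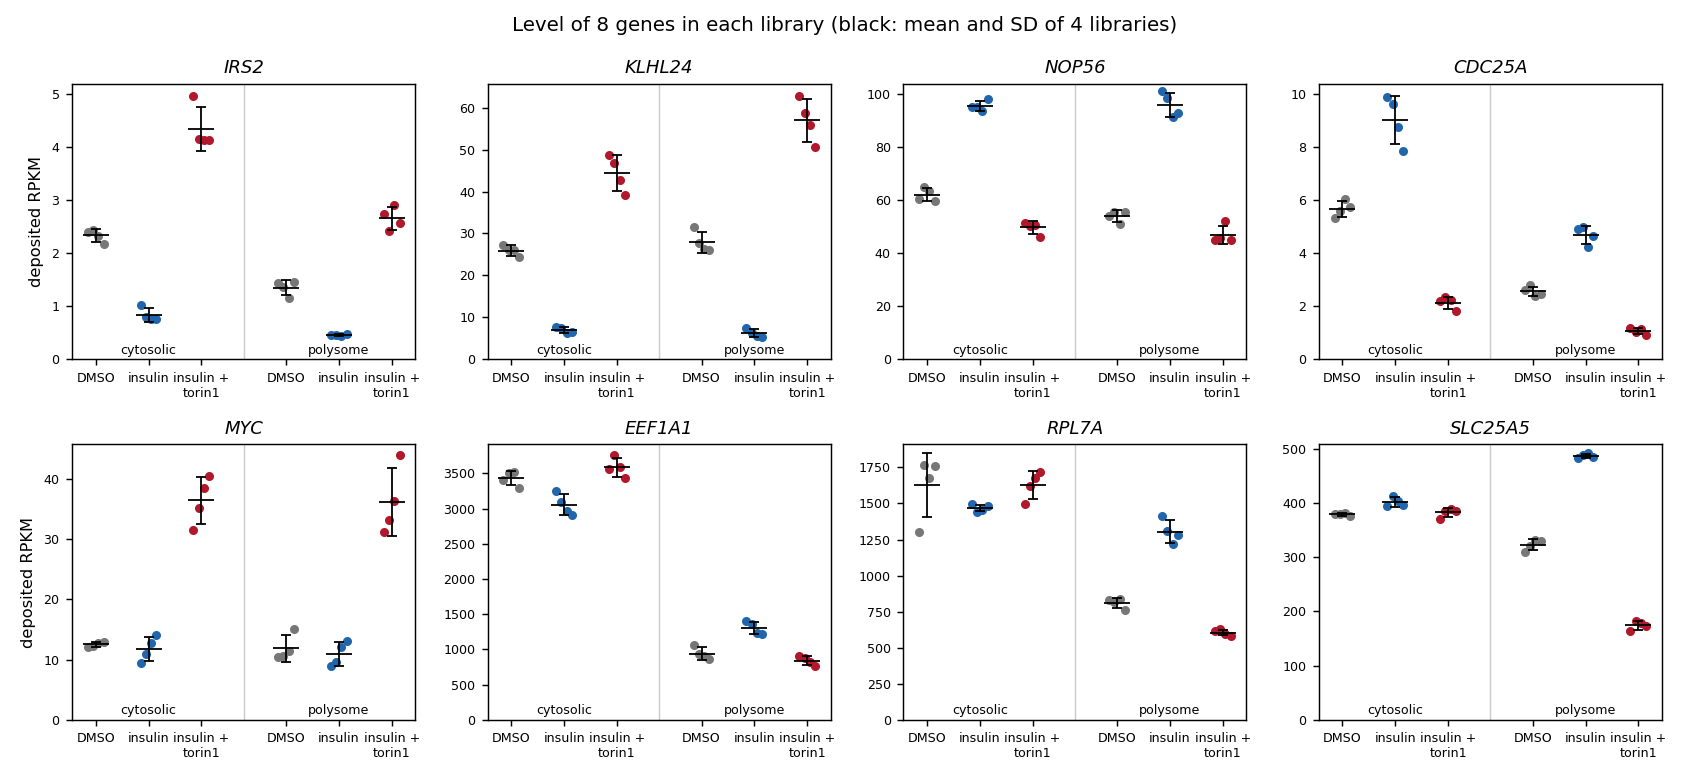
RPKM of 8 genes in each library, for the 3 treatments in cytosolic and polysome-associated RNA; points are the 4 libraries of a group and black marks the mean and SD. RPL7A and SLC25A5 were highest with insulin and lowest with torin1 on polysomes (RPL7A 1310 ± 82.5 and 605 ± 20.1).

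Adding torin1 changed 5760 genes in polysome-associated RNA (2903 up, 2857 down, or 3776 and 4820 with a replicate block) and 3928 in cytosolic RNA (1947 up, 1981 down, or 6768 with a replicate block, 3070 and 3698). Efficiency changed for 572 genes (216 up, 356 down). A replicate block gave 4302 and turned the balance, with 2282 up and 2020 down. In the fit without a block 74 of the 356 falls were ribosomal protein or other TOP genes. The balance of efficiency changes depended on the scaling too, with 644 up and 245 down for library totals, 612 and 236 for RPKM as deposited, and 88 and 329 for median-ratio factors. That count was 350 without insulin cytosolic replicate 1 and 1398 without insulin polysome replicate 1, and 6 of 16 libraries moved it by more than 1.5 times. Polysome and cytosolic changes correlated across genes with r = 0.774. Of the changed genes, 2959 moved together in both fractions and did not pass in efficiency. Another 483 changed in efficiency together with polysome-associated RNA (169 up, 314 down), and 78 changed in cytosolic RNA with an opposite change in efficiency. With a replicate block the classes of 483 and 78 held 3462 and 5.5e+02 genes (the latter rounded to 2 digits). Without insulin cytosolic replicate 1 they held 307 and 34, and without insulin polysome replicate 1 they held 1155 and 188, with 6 and 10 of 16 libraries moving them by more than 1.5 times.

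The same genes were often called in opposite directions when insulin was given and when torin1 was added, but both comparisons share the insulin libraries. In polysome-associated RNA 3238 genes did so, NOP56 and KLHL24 among them, where independent calls would give 951. Simulations without an effect gave 0, but they call almost no gene and so set no expected overlap. With the insulin libraries split between the 2 comparisons the count was 1674 to 2613 over 6 splits, and a replicate block gave 6540. In cytosolic RNA 1860 genes did so (417 from independent calls, 795 to 1459 over the splits). In efficiency 75 did so (2.58 from independent calls, 10 to 58 over the splits). Of these, 74 rose with insulin and fell with torin1. Ribosomal protein or other TOP genes made up 40 of the 75, SLC25A5 and RPL7A among them. The highest split counts came from splits that parted numbers 1 and 2 from 3 and 4. Such splits unbalance the component that same-numbered libraries share. They gave up to 58 in efficiency, 2613 on polysomes and 1459 in cytosolic RNA. The splits that kept 1 with 4 and 2 with 3 gave 16 and 10 in efficiency. Over all tested genes the covariance of the efficiency changes was -0.0322, against -0.028 in simulations with shared libraries and no effect. The difference was -0.00424. With the insulin libraries split, the covariance was -0.0232, -0.0177, -0.00175, -0.0217, -0.00443 and 0.00629 over the 6 splits. The first and the last of these values are from the splits that parted numbers 1 and 2 from 3 and 4. The simulations moved both fractions of a lysate together but dealt lysates at random over treatments and numbers. They thus did not keep the component shared by same-numbered libraries balanced over treatments. The simulated covariances are therefore an unlike reference, and -0.028 cannot decide the question for all genes. The reversal in efficiency is thus shown for called genes, and over all genes it stays open. Without splitting, the covariance was -0.222 against a simulated -0.0302 on polysomes and -0.133 against -0.0317 in cytosolic RNA. The cytosolic count was 1225 without insulin cytosolic replicate 3 and 1230 without replicate 4. The efficiency count was 140 without insulin and torin1 cytosolic replicate 1, and 10 of 24 libraries moved it by more than 1.5 times.

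The comparison of insulin and torin1 with DMSO asked what differed from starved cells when insulin was given while mTOR was inhibited. MYC was 2.99-fold higher in polysome-associated RNA (1.58 ± 0.16, adjusted p = 3.6e-07) and 3.01-fold higher in cytosolic RNA. AREG, a ligand of the EGF receptor, rose by 1.38 ± 0.16 in polysome-associated RNA, and ACKR3, a chemokine receptor, by 1.45 ± 0.22 in cytosolic RNA. CDC25A fell by 1.32 ± 0.09 and by 1.37 ± 0.09 in the 2 fractions. IRS2 was 1.93-fold higher than in starved cells (0.95 ± 0.10) and KLHL24 2-fold higher (1.00 ± 0.10) in polysome-associated RNA.

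Of 28 FOXO and insulin feedback genes, 16 rose and 2 fell in polysome-associated RNA, SESN1 and PIK3R3 (20 and 3 adjusted over the list alone, adjusted p = 2.7e-13). In cytosolic RNA 14 rose and 2 fell (18 and 2 adjusted over the list alone, adjusted p = 2.1e-12). Of 41 G1/S and DNA replication genes, 19 fell and 0 rose in each fraction (23 and 0, and 21 and 1, adjusted over the list alone, and 30 and 1 on polysomes with a replicate block, with adjusted p = 1.8e-13 and 2.1e-12). CCNE1 fell by 1.32 ± 0.12 in polysome-associated RNA and GINS1, part of the replicative helicase, by 0.74 ± 0.06 in cytosolic RNA. Of 18 measured immediate-early and ERK targets, 9 rose and 0 fell in cytosolic RNA (10 adjusted over the list alone, adjusted p = 2.2e-10). DUSP4, a phosphatase that inactivates ERK, rose by 1.03 ± 0.10 and the transcription factor EGR3 by 1.21 ± 0.14. In polysome-associated RNA 8 of this list rose and 0 fell (9 adjusted over the list alone, adjusted p = 3.2e-08, or adjusted p = 0.066 with an estimated correlation). Oestrogen receptor targets had 10 rises and 1 fall, FKBP4, in each fraction (10 and 1 on polysomes and 12 and 1 in cytosolic RNA adjusted over the list alone, adjusted p = 8.9e-06 and 9.9e-08), with NRIP1, a nuclear receptor corepressor, at 1.02 ± 0.11 in polysome-associated RNA. In insulin and torin1 cytosolic RNA the median log2 deviation climbed from replicate 1 to 4 for ERK targets (0.152 to 0.773) and oestrogen receptor targets (0.117 to 0.516). Part of these cytosolic rises can thus lie along the variation that same-numbered libraries share. The size of that part was not estimated. Of 26 chaperone genes 12 fell and 0 rose in polysome-associated RNA (13 and 0 adjusted over the list alone, 20 and 0 with a replicate block, adjusted p = 1.5e-08, or adjusted p = 0.066 with an estimated correlation), with DNAJA1 at -1.04 ± 0.10. Proteasome subunits fell there too, 12 of 32 with 0 rises (14 and 0 adjusted over the list alone, 24 and 0 with a replicate block, adjusted p = 3.3e-05, or adjusted p = 0.14 with an estimated correlation).

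Efficiency against DMSO fell for SLC25A5 (-0.98 ± 0.06, adjusted p = 4e-09), YBX1 (-0.99 ± 0.08), CCNI, a cyclin-like protein (-1.17 ± 0.14), HSPA8 (-1.09 ± 0.13) and PABPC4 (-0.87 ± 0.09). Of 30 other TOP mRNAs 5 fell and 0 rose (12 fell adjusted over the list alone, adjusted p = 2.1e-20). Of 79 ribosomal protein genes RPL7A, RPS7 and UBA52 fell and 0 rose (15 fell and 1 rose adjusted over the list alone, adjusted p = 4.8e-13, or adjusted p = 0.19 with an estimated correlation), and RPL7A did not pass with median scaling in limma. In polysome-associated RNA 12 ribosomal protein genes fell and 2 rose, RPL41 and RPS27 (12 and 2 adjusted over the list alone, 34 and 2 with a replicate block), with adjusted p = 0.0066, or adjusted p = 0.46 with an estimated correlation.

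In polysome-associated RNA 2142 genes differed from DMSO (923 up, 1219 down), or 4967 with a replicate block (2062 and 2905), and the balance was 949 up and 825 down for RPKM as deposited. In cytosolic RNA 1595 differed (667 up, 928 down), with 513 up and 1187 down for library totals. That count was 640 without DMSO cytosolic replicates 2 and 3, 2508 without insulin and torin1 cytosolic replicate 1 and 998 without replicate 4 of that group. Efficiency differed for 70 genes (4 up, 66 down), 8 up and 18 down for RPKM as deposited, and 3 up and 12 down with quantile normalisation. The 4 rises included HMGB2 (0.44 ± 0.10), MRFAP1L1 and TSC22D1, which did not pass without several single libraries. The count of 70 was 16 without DMSO cytosolic replicates 2 and 3, and 17 to 166 when 1 library was left out (without insulin and torin1 polysome replicate 3 and without DMSO polysome replicate 2), with 12 of 16 libraries moving it by more than 1.5 times. The 2 fractions correlated across genes with r = 0.361, and 960 genes moved together and did not pass in efficiency. Another 63 changed in efficiency with polysome-associated RNA (4 up, 59 down), and 7 changed in cytosolic RNA with an opposite change in efficiency. The 63 became 17 without insulin and torin1 polysome replicate 3 and 139 without DMSO polysome replicate 2, with 10 of 16 libraries moving it by more than 1.5 times. The 7 became 0 without DMSO cytosolic replicate 2 and 26 without DMSO polysome replicate 2, and 16 of 16 libraries moved it by that much.

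**Figure D4:**
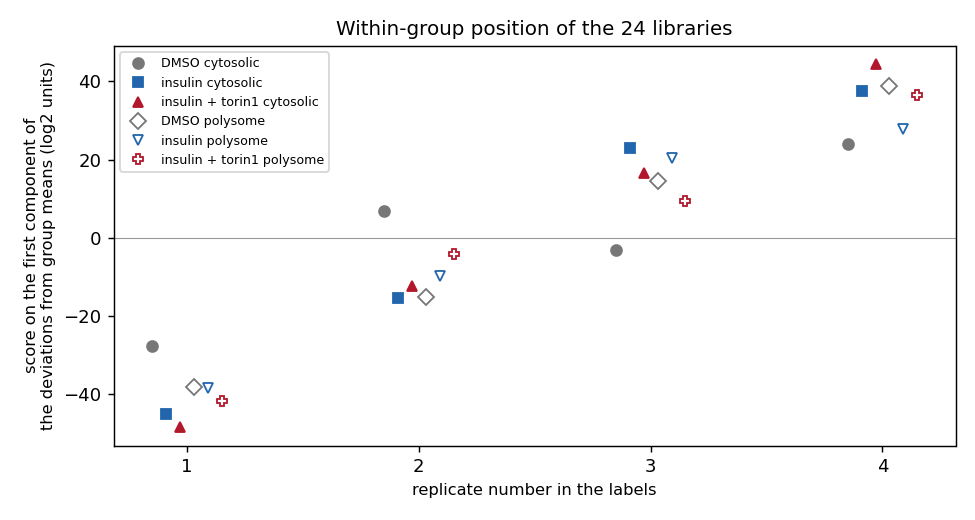
Score of each library on the first component of the variation within groups (75.7% of that variance), by replicate number, for the 6 groups. Same-numbered libraries score alike, except DMSO cytosolic replicates 2 and 3, whose correlation with the same numbers of other groups was -0.29 to -0.0715.

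Of the 207 list tests, 26 passed with an estimated correlation between genes. In the 3 comparisons the 26 included the FOXO and insulin feedback genes in both fractions each time, the ribosome biogenesis genes in both fractions for insulin and for torin1 against insulin, and the G1/S genes in both fractions for torin1 against insulin and against DMSO. For efficiency they included the ribosomal protein and other TOP lists for insulin and for torin1 against insulin, and the other TOP list for torin1 against DMSO. The rest were ribosomal proteins on polysomes under insulin, SREBP and ATF4 targets in cytosolic RNA under insulin, other TOP mRNAs on polysomes for torin1 against insulin, ERK targets in cytosolic RNA and oestrogen receptor targets in both fractions for torin1 against DMSO. A replicate block together with an estimated correlation left the G1/S genes at adjusted p = 0.18 on polysomes and 0.09 in cytosolic RNA for torin1 against insulin and 0.09 on polysomes against DMSO. Other calls lost in that fit, where numbers pair, were ribosomal proteins on polysomes under insulin (0.35), other TOP mRNAs (0.18) and ribosome biogenesis genes (0.07) on polysomes for torin1 against insulin, and oestrogen receptor targets on polysomes against DMSO (0.098). Ribosomal protein values are uncertain because pseudogenes and paralogs share their sequence, and a symbol with a slash is a row with several gene names.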

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

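Of the tests in this section, the one of GC content and transcript length as a source of the within-group axis was chosen after the result was seen. A Dixon test of 264 groups of 4 values picked 12 values, where about 13.2 are expected by chance at 1 in 20. TPT1 was at 656 RPKM in insulin and torin1 cytosolic replicate 1 (others 554 to 557), and IRS2 at 1.02 RPKM in insulin cytosolic replicate 1 (0.752 to 0.793) and at 4.97 in insulin and torin1 cytosolic replicate 1 (4.13 to 4.15). As median log2 deviations of lists, the other TOP mRNAs were at -0.62 in DMSO polysome replicate 4 (-0.41 to -0.39). SREBP targets were at 0.27 in DMSO polysome replicate 3 (0.09 to 0.11), -0.16 in insulin cytosolic replicate 1 (0.01 to 0.04) and 0.52 in insulin polysome replicate 2 (0.3 to 0.33). In insulin and torin1 polysome replicate 1, ATF4 targets were at -0.14 (0.04 to 0.06), ribosome biogenesis genes at -0.32 (-0.13 to -0.12) and oestrogen receptor targets at -0.17 (0.2 to 0.25). In DMSO cytosolic RNA, mitosis genes were at 0.03 in replicate 4 (0.09 to 0.1) and chaperones at -0.08 in replicate 1 (-0.14 in the nearest others). These 12 are no more than chance gives, though 8 of the 12 lie in replicates numbered 1. Polysome-associated and cytosolic RNA passed in opposite directions for 14 genes under insulin (13 up on polysomes), 77 with torin1 against insulin (66 down on polysomes, or 384 in all with a replicate block) and 10 with torin1 against DMSO (10 down on polysomes).

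The first pattern is an axis of variation within groups that libraries of the same number share. It held 75.7% of the within-group variance, against 3.76% for the next component, and histone genes such as HIST1H4J lay at its high end. Treatments were shifted along it too, when scores kept the group differences. On polysomes scores were -24.22 to 52.61 with DMSO, 6.608 to 72.99 with insulin and -31.19 to 47.11 with torin1 added. In cytosolic RNA they were -72.26 to -20.65, -52.07 to 30.3 and -66.3 to 26.57. Changes of lists that follow the axis, such as histones, glycolysis genes, ERK targets and oestrogen receptor targets, can therefore hold part of this shift. Its size was estimated for the TOP lists only. Loadings ranked with GC content at r = 0.87 over 11196 genes. Removing each library's trend on GC content and length lowered the share from 76.3% to 40.3% of the variance that remained. So much of the axis followed these properties. The share left lay just over the bar for calling them the source, and that bar was set after the result was seen. Whether they were the source thus stays open. Sequencing depth was excluded (r = 0.132, permutation p = 0.6), as were a few genes with most of the counts (75.7% without the 50 genes that hold 11.9% of counts). A difference in library preparation between replicate numbers could leave such an axis, and DMSO cytosolic replicates 2 and 3, at r -0.29 to -0.0715 with their numbers, may have been prepared apart or exchanged, which was not tested and would change blocked values with DMSO cytosolic RNA.

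The second pattern is the efficiency of ribosomal protein and other TOP mRNAs, which rose with insulin (median 0.50) and fell with added torin1 (median -0.91). With a replicate block and a correction for GC content and length the median under torin1 was -0.89, so these were excluded as the source. For the fall under torin1 the within-group axis (0.02 predicted) was excluded too. The scaling test used the median relative to all genes over 6 scalings. A factor per library cannot move that value, so only quantile normalisation could change it. It was -0.58 there, with 28 members falling against 74 in the main test. The median itself was -0.57 with quantile normalisation and as low as -0.92 in other scalings, so scaling changed the size of the fall and not its direction. The rise with insulin was not put to the scaling test and depended more on scaling, with a median relative to all genes of 0.3 and 2 members passing with quantile normalisation, against 40 in the main test. A hypothesis, not tested here, is that initiation on mRNAs with a 5' terminal pyrimidine tract was inhibited, which these libraries cannot separate from other effects of torin1.

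The third pattern is the cytosolic level of the same mRNAs, which rose under added torin1 (median 0.24) while their polysome-associated RNA fell (median -0.68). The median was 0.23 with the replicate block and correction for GC content and length, and the axis predicted 0.01, so both were excluded. Scaling could not be told apart, because quantile normalisation left 0.11 relative to all genes while the next smallest was 0.28. Stabilisation of TOP mRNAs that are not translated might raise their cytosolic level, but a relative loss of other mRNAs would look the same.

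Splitting the 8 lysates of a comparison in the other ways asked whether chance could reach the counts. Both fractions of a number were moved together as 1 lysate, which the labels do not state. The bar for excluding chance was a share of splits under 0.05. With 35 splits the lowest possible share is 1 of 35, which any largest count reaches. No correction was made for the number of counts tested. For genes changed in polysome-associated RNA under insulin, chance could not be excluded, as 2 of 35 splits were as large (3808, highest other 5850). The split with 5850 calls kept 3 of the 4 insulin lysates together, so it carried part of the treatment, and the source of its calls was not tested. Among the 8 splits that part every replicate number the highest other was 0. Under insulin the bar was met for efficiency (85 against 0) and for the translation class (78 against 0), each 1 of 35. Cytosolic RNA (2456 against 2410) and the abundance class (1839 against 1642) also met the bar, each 1 of 35. Leaving out 1 library took these 2 counts as low as 1457 and 1233, below those of the other split, so chance is not excluded for them. The buffering class was 5 against 0 (1 of 35). For the list tests under insulin chance was not excluded (5 of 35, 31 against 35). With torin1 against insulin the bar was met (1 of 35) in cytosolic RNA (3928 against 2453, or 0 among splits that part every number). The same held for efficiency (572 against 0) and the 3 classes (483, 78 and 2959, each against 0). On polysomes (5760 against 4979, or 1 among splits that part every number) the bar was met. The count there was 4978 without insulin and torin1 polysome replicate 1, so chance is not clearly excluded. The list tests met the bar by a margin of 1 test (38 against 37), so chance is not excluded for them. With torin1 against DMSO the bar was met (1 of 35 each) on polysomes (2142 against 0) and in efficiency (70 against 0). The same held for the translation and abundance classes (63 and 960, each against 0), but not for the list tests (2 of 35, 33 against 34). Cytosolic RNA met the bar (1 of 35, 1595 against 1497). That count was 998 without insulin and torin1 cytosolic replicate 4, so chance is not excluded for it. The buffering class of torin1 against DMSO was 7 against 0 (1 of 35). The other splits put the treatment into the spread within groups, which can lower their counts, so a highest other of 0 is a weak bar for efficiency and the classes. Efficiency was called for 0 genes in every other split of the 3 comparisons. Meeting the bar therefore does not by itself exclude chance. Single libraries moved the 5 to between 1 and 15 and the 7 to between 0 and 26, so these 2 counts are uncertain.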

How the results depend on the processing

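The number of changed genes depended most on the replicate block and, for efficiency, on scaling, filter and single libraries, while directions of named genes mostly did not. Over 17 other settings 10686 values of named genes were recomputed: 9797 were the same, 571 weaker, 305 stronger and 13 reversed. Weaker means a call lost and stronger a call gained. A value counted as reversed if its sign differed and it passed in either fit. Where neither value passed, a change of sign counted as the same. Over 24 libraries left out in turn, 6666 of 7056 were the same, 314 weaker, 76 stronger and 0 reversed. limma on RPKM was the main test of the plan. The use of edgeR on counts as the main test, and so of limma on RPKM + 0.5 with median scaling as an alternative, was settled after the unit of the file was seen. DESeq2, median-ratio factors, the block with GC content and length, leaving out DMSO cytosolic replicates 2 and 3, and list tests with the block and an estimated correlation together were added after the data were seen. The cause of each shift was not tested. In what follows T is insulin and torin1, and classes are translation, buffering and abundance.

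In limma on log2(RPKM + 0.1), efficiency changed for 374 genes for T against insulin (77 up, 297 down) and 24 for T against DMSO. The buffering class held 8 (insulin), 44 (T against insulin) and 1 (T against DMSO), and the translation class of T against DMSO 23. With RPKM + 1, efficiency for T against DMSO was 23, its translation class 21 and its buffering class 2. With RPKM + 0.5 and median scaling, efficiency was 376 (78 up, 298 down) for T against insulin and 23 for T against DMSO. The buffering class was 8, 48 and 2 over the 3 comparisons, the translation class 319 (T against insulin) and 21 (T against DMSO). As deposited without scaling, efficiency was 45 (insulin) and 26 (T against DMSO), translation 43 and 23 for these, buffering 2, 132 and 3, and 40 genes changed efficiency in opposite directions under insulin and torin1. With quantile normalisation, efficiency was 15, 228 and 15, and T against DMSO on polysomes 1156. Translation was then 14, 180 and 13, buffering 1, 36 and 2, abundance for T against DMSO 540, and opposite efficiency 14. With a trended variance prior, efficiency for T against DMSO was 28, translation 26 and buffering 2.

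Without a filter, efficiency was 33, 237 and 12, translation 33, 212 and 12, buffering 0, 21 and 0 with edgeR, and opposite efficiency 31. With a mean RPKM of at least 5, efficiency under insulin was 181, translation 160, buffering 20, buffering of T against DMSO 4, and opposite efficiency 147. With library totals, efficiency was 55, 889 (644 up, 245 down) and 23, buffering 1, 141 and 1, and translation of T against DMSO 22, with the median of all genes in efficiency under insulin at -0.105. With median-ratio factors, efficiency of T against DMSO was 25, its translation 25, and buffering 8, 48 and 0. With DESeq2, efficiency under insulin was 140, translation 126 and buffering 12, and buffering of T against DMSO 12.

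With a replicate block, insulin changed 7739 genes on polysomes, 6838 in cytosolic RNA (3983 up, 2855 down) and 875 in efficiency (363 up, 512 down). T against insulin changed 6768 in cytosolic RNA and 4302 in efficiency, and T against DMSO 4967, 5743 (3220 up, 2523 down) and 3199 (960 up, 2239 down). Translation was 724, 3462 and 1481, abundance 5295 (insulin) and 2230 (T against DMSO), and buffering 1.1e+02 and 5.5e+02 (both rounded to 2 digits) and 1498. Opposite changes were 6540, 4414 and 697. Genes that passed in opposite directions in the 2 fractions were 91, 384 and 296. The balance of up and down turned against the main test in cytosolic RNA under insulin, in efficiency under insulin and in cytosolic RNA for T against DMSO. It also turned on polysomes under insulin (4118 up, 3621 down). For T against insulin it turned on polysomes (3776 up, 4820 down) and in efficiency (2282 up, 2020 down). For comparisons with DMSO cytosolic RNA the block rests on numbers that do not pair, and 13 of 24 libraries correlated best with their own number. With only the 8 libraries compared, insulin changed 2152 and T against DMSO 842 on polysomes, with 1943 opposite. With paired lysates, efficiency was 711, 4104 and 3046, and 594 opposite. In analysis of partial variance it was 738, 4393 and 1978, and 651 opposite. With block and GC and length correction, counts were 6342, 6012 and 1465 (insulin), 7369 and 2871 (T against insulin, cytosolic and efficiency) and 6012, 5572 and 2001 (T against DMSO). Translation was 932, 2044 and 1260, buffering 405, 475 and 607, abundance 3892, 4586 and 3227, and opposite changes 5210, 4588 and 862.

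Without DMSO cytosolic replicates 2 and 3, cytosolic changes were 989 (insulin) and 640 (T against DMSO), efficiency 30 and 16, translation 30 and 16, buffering 0 and 0 in edgeR, and abundance 896 and 524. Leaving out 1 library moved the following counts, most by more than 1.5 times, and the lowest and highest are given with them. Cytosolic changes under insulin were 1457 without insulin cytosolic 4, 1473 without 3 and 3699 without 1. Efficiency under insulin was 53 without insulin cytosolic 4, 55 without 3, 130 without 2, 137, 155 and 136 without DMSO polysome 1, 2 and 3, and 139 and 141 without insulin polysome 1 and 4. Efficiency of T against insulin was 350 without insulin cytosolic 1, 1398 without insulin polysome 1, 1267 without T cytosolic 1, and 361, 369 and 366 without T polysome 1, 2 and 3. For T against DMSO, cytosolic changes were 998 without T cytosolic 4 and 2508 without T cytosolic 1. Its efficiency was 34, 35 and 20 without DMSO cytosolic 1, 2 and 3, 45, 166 and 37 without DMSO polysome 1, 2 and 4, 41, 38 and 45 without T cytosolic 2, 3 and 4, and 25, 20 and 17 without T polysome 1, 2 and 3. Over single libraries the translation class ranged over 52 to 139 (insulin), 307 to 1155 (T against insulin) and 17 to 139 (T against DMSO), and buffering over 1 to 15, 34 to 188 and 0 to 26. Opposite cytosolic changes were 1225 and 1230 without insulin cytosolic 3 and 4 and 2283 without insulin cytosolic 1. Opposite efficiency changes were 51 without insulin cytosolic 3, 127 without DMSO polysome 2 and 140 without T cytosolic 1. They were also more than 1.5 times the main 75, and below 127, without DMSO polysome 1 or 3, insulin cytosolic 2, insulin polysome 1 or 4, T cytosolic 2 or 3, or T polysome 4. Depth limits counts of low genes most, and the deepest and shallowest libraries differ by 4 times.

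The list tests passing were 26 with an estimated correlation, 96 with a replicate block and 13 with both. The 13 were the FOXO and insulin feedback genes in both fractions of the 3 comparisons, ribosome biogenesis genes in both fractions under insulin and in cytosolic RNA for T against insulin, and the efficiency of ribosomal protein and other TOP mRNAs under insulin and for T against insulin. With the preset correlation and where numbers pair, the block ended the calls of the nuclear non-coding RNAs on polysomes (adjusted p = 0.086) and of the respiratory chain genes in cytosolic RNA (adjusted p = 0.093), both for T against insulin. The block ended the call of no gene that passed without it and changed no other list call there.

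Reversed values were EEF1A1 in cytosolic RNA for T against insulin (-0.03, quantile), INSR in efficiency for T against insulin (0.94, analysis of partial variance) and 11 with block and GC and length correction. These were FDPS/RUSC1 on polysomes (-0.03) and in cytosolic RNA (-0.13), TPT1 (0.15), TFAM (0.14) and LDLR (-0.13) on polysomes, FADS1/FADS2 (-0.03) and EGR3 (0) in cytosolic RNA, all under insulin. For T against insulin they were TFAM (-0.24), LDLR (0.26) and BCL2L1 (0.20) on polysomes and BCL2L1 in cytosolic RNA (0.12).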

Other observations

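Of 76 mitochondrial ribosomal protein genes, 19 rose under insulin on polysomes, 2 fell and 55 did not pass (MRPS6/SLC5A3 and MRPS25/NR2C2 fell, 18 and 2 adjusted over the list alone, 42 and 7 with a replicate block, adjusted p = 0.0025, or adjusted p = 0.29 with an estimated correlation) and 31 fell with torin1 against insulin (MRPS25/NR2C2 up, 44 not passing, 30 and 1 adjusted over the list alone, 49 and 4 with a replicate block, adjusted p = 0.0031, or adjusted p = 0.24 with an estimated correlation). Of 75 respiratory chain genes, 23 fell with torin1 against insulin on polysomes, COX6C rose and 51 did not pass (23 and 1 adjusted over the list alone, 44 and 6 with a replicate block, adjusted p = 0.0077, or adjusted p = 0.43 with an estimated correlation). The median of that list was -0.2, and it turned to 0.02 with quantile normalisation. Replication-dependent histones, 51 measured, had large medians and few passing members. Histone genes lay at the high end of the within-group axis, along which treatments were shifted, and its part in these changes was not tested. On polysomes the median under insulin was 0.61 with HIST1H4C as the 1 rise (47 with a replicate block, adjusted p = 0.00041, or adjusted p = 0.58 with an estimated correlation). In cytosolic RNA it was 0.9 with torin1 against DMSO, with 5 rises (1 adjusted over the list alone, adjusted p = 3.7e-08, or adjusted p = 0.39 with an estimated correlation). They had 7 rises in cytosolic RNA with torin1 against insulin (4 adjusted over the list alone, 35 with a replicate block, adjusted p = 0.011, or adjusted p = 0.68 with an estimated correlation), with HIST1H1D at 1.12 ± 0.20. Of 11 nuclear non-coding RNAs, NEAT1 fell by 1.14 ± 0.10 and MALAT1 by 0.78 ± 0.19 in cytosolic RNA under insulin, and 9 did not pass (adjusted p = 0.048, or adjusted p = 0.15 with an estimated correlation). Of 38 mTOR pathway genes, 13 fell under insulin on polysomes and 2 rose, EIF4A1/SENP3 and LARP1 (13 and 3 adjusted over the list alone, 18 and 11 with a replicate block, adjusted p = 0.0077, or adjusted p = 0.1 with an estimated correlation), with DEPTOR, an inhibitor of mTOR, at -0.65 ± 0.07. These members were chosen after their values were seen where counts were 5 or fewer.

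For some genes cytosolic RNA passed with torin1 against insulin and polysome-associated RNA did not. CKS2, a subunit of cyclin-dependent kinases, was at -0.4 in cytosolic RNA and 0.12 on polysomes (efficiency 0.51 ± 0.14). WASF2, which drives actin assembly, was at 0.5 and -0.03 (efficiency -0.53 ± 0.10). These 2 were chosen after their values were seen.

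A hypothesis was that genes outside the TOP lists whose efficiency fell with added torin1 more often have an annotated 5' end of C followed by pyrimidines, as a TOP-like start could make an mRNA sensitive to mTOR. Such starts occurred in 16 of 240 falls (6.67%) and 241 of 9736 other genes (2.48%), an odds ratio of 2.81 (95% CI 1.56 to 4.77, Fisher p = 0.00047, adjusted p = 0.00095 over 2 tests). Within 4 groups of mean RPKM the odds ratio was 2.9 (exact p = 4e-04), and for efficiency rises it was 0.583 (3 of 196, p = 0.49). List members had such a start in 19.3%, so most of them did not count as TOP by their annotated ends. Whether the annotation or the make-up of the lists is the reason was not tested. CCNI, KDELR1, TGFBI, CAMK2G, CCT3 and TOMM22 are candidates among the 16, chosen after their values were seen. Mapped 5' ends of the transcripts in these cells would test this directly.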
